A study of Homo sapiens with 3 samples.

How the data were processed

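mRNA sequencing libraries from 3 samples of NCI-H23 cells were used: 1 library from cells given control siRNA and 2 libraries from cells given siRNA against USP16. The control was taken from its treatment label, which reads control, and the USP16 siRNA samples from their titles. The labels number the USP16 siRNA libraries 1 and 2 without saying whether these are different siRNAs or different cultures, so p-values measure only the spread between these samples, which may be technical. The count column of the second USP16 siRNA sample carries the number 6 in its header where its label has 2, and the sample was used as labelled.

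The deposited files hold whole-number counts of reads per gene for 50868 Ensembl genes, with no normalization visible in the values. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and the human genome build hg38, with no role given for either tool. The counting method, its use of strand, its treatment of reads that match several genes and the gene annotation are not given in the sources used here. Per the labels' protocols, total RNA was purified, treated with DNase and made into libraries with a kit for mRNA. Reads from overlapping genes, antisense partners and near-identical copies therefore cannot be told apart with certainty. An example is the pseudogene EEF1A1P5, with 121966, 99513 and 129642 counts in the control and the 2 knockdown libraries, against 30701, 24364 and 31757 for its parent EEF1A1, which encodes a translation elongation factor.

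Gene symbols were those of the files. Of the gene identifiers, 50111 (98.5%) matched GENCODE release 29, which is on the same build and gave positions, transcript lengths and GC content, and 375 rows repeated the symbol of an earlier row. No row lacked a gene. The libraries held 14007161, 13956382 and 15071179 counts. No pair of libraries held identical values, and the chi-square statistic of the knockdown libraries against each other was 62.5 per degree of freedom over genes with at least 20 counts in the pair, so they were treated as separate samples.

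Genes with too few counts were removed with edgeR's filterByExpr, which left 17287 genes. Counts were scaled by trimmed means of M-values (TMM factors 0.952, 1.02 and 1.03). The knockdown libraries were compared with the control by the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 control library the fit had 1 residual degree of freedom, and the control was assumed to vary like the knockdown libraries. Fold changes per library are on the scale of log2 CPM, counts scaled to a common library size, with a prior count of 2, and a mean of the 2 values is given with its SD. That SD leaves out the variation of the shared control, so it understates the uncertainty of the change. Genes changed at least 2-fold in the same direction in both knockdown libraries were counted as a description that needs no estimate of the spread. Where a gene had 0 counts in one group, the fold is a lower bound against a floor of 3 counts in each library of that group. Intervals are 95% exact Poisson intervals for counts, exact binomial intervals for ratios of counts and Wilson intervals for shares of counts. They and the floor cover counting error only.

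Gene lists, 39 in all, were fixed before the data were examined and tested with camera (limma 3.58.1) at its preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Both rest on the 1 residual degree of freedom, so hardly any list could pass them. A call lost there therefore says little about a list. The percentile of each list's median among 10000 random lists matched on mean expression describes these libraries only. Genes were also adjusted over the list alone. The rule for genes to name was fixed at the same time: USP16, 8 genes of interest, the 10 genes with the largest and the 10 with the lowest mean log2 fold change among genes with a mean of at least 100 counts, 2-fold in both libraries and past the threshold, and up to 4 members of each list with the largest change. Too few genes passed the threshold, so the 10 of each direction were filled by the same rule without the test. Some genes that the rule names are not reported here. The 2 knockdown libraries share their control, so 20 simulations without an effect gave the agreement that sharing alone would produce if all libraries varied alike. The pairs of libraries differed in variance, so the simulations cannot give the agreement from sharing for these libraries.

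Alternatives fixed in advance were no filter on low counts, a minimum mean of 100 counts, median-ratio size factors, DESeq2 1.42.0, other pseudocounts, a prior count of 10 and leaving out each knockdown library. Removing readthrough genes with the genes they span, and setting each knockdown library alone against the others, were added after seeing the data. Readthrough genes were picked by a symbol that joins those of 2 genes, so a gene without such a symbol, ENSG00000270299 among them, was kept. The procedure was tested on simulated data: counts drawn for this comparison over 17287 genes, with 50 genes changed at each size, gave back 6% of 2-fold, 56% of 4-fold, 94% of 8-fold and 100% of 16-fold changes. Among the other genes 8 were called. These others include the 26 genes of the shifted list below, so not all 8 need be false. In the same simulation a list of 26 genes shifted by -0.5 was called with an adjusted p of 0.00256 (camera), and 0 of 38 lists without a shift were called. Its genes were drawn independently of each other, so it cannot show how often lists are called falsely where their members vary together. All libraries varied alike in it, which the real ones did not, so its recovery rates may not carry over. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.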

Results

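The transcriptome of NCI-H23, a human lung adenocarcinoma cell line, was profiled after transfection with control siRNA or with siRNA against USP16, which encodes a deubiquitinase that removes ubiquitin from histone H2A. The design asks which transcripts differ in level when USP16 is knocked down. There was 1 control library with 14007161 counts and there were 2 knockdown libraries, numbered 1 and 2 as in their labels, with 13956382 and 15071179 counts. Counts above 0 were found for 23127 genes in the control and for 23823 and 24616 genes in the knockdown libraries. Mitochondrial transcripts took 8.56% of counts in the control (Wilson 95% interval 8.54 to 8.57), 7.41% in knockdown library 1 (7.40 to 7.43) and 7.33% in knockdown library 2 (7.31 to 7.34). In what follows, 3 counts given together are those of the control, knockdown library 1 and knockdown library 2, and a pair of values for a gene is its log2 fold change against the control in knockdown library 1 and then library 2. For a gene list the pair holds the medians of these changes.

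USP16 itself lies on chromosome 21 at positions 29024629 to 29054488 of hg38, on the plus strand. It had 632 counts in the control and 109 and 245 counts in the knockdown libraries. The scaled level was 47.5 CPM in the control (exact Poisson 95% interval 43.8 to 51.3), 7.69 in knockdown library 1 (6.32 to 9.28) and 15.8 in knockdown library 2 (13.8 to 17.9). These levels are 83.8% and 66.8% lower than in the control. The log2 change was -2.60 and -1.58, with a mean of -2.09 ± 0.72 (SD, n = 2). Among the 14 H2A deubiquitinases measured, USP16 passed the threshold when adjusted over the list alone (edgeR, adjusted p = 0.0198) and not over all genes tested (adjusted p = 0.561). Over all genes its adjusted p ranged from 0.0188 with no filter on low counts to 0.869 with a minimum mean of 100 counts. BAP1, the catalytic subunit of another H2A deubiquitinase complex, was at -0.17 and 0.00, and MYSM1, a further member of the group, at -0.05 and 0.55.

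Over the whole transcriptome, 3 genes fell and 0 rose past an adjusted p of 0.05 (edgeR quasi-likelihood test, 17287 genes), while 844 genes had an unadjusted p under 0.05 where chance alone gives about 864. The 3 that fell are unusual annotations. ATP6V1G2-DDX39B, a readthrough gene on chromosome 6, had 637, 0 and 0 counts (adjusted p = 0.000392) and was at least 226-fold lower in knockdown library 1 and at least 248-fold lower in knockdown library 2. The gene with the identifier ENSG00000270299, on chromosome 20, overlaps both SCRT2 and SRXN1 on the same strand. It had 142, 0 and 0 counts (edgeR, adjusted p = 0.0133) and was at least 50.4-fold and 55.3-fold lower. RP11-311C24.1, a noncoding RNA that overlaps the 3' end of NFAT5 on chromosome 16, had 110, 1 and 1 counts (adjusted p = 0.0203), a control to knockdown ratio of 117 (20.6 to 4670) and 129 (22.6 to 5120). The genes that these annotations overlap did not all go the same way: DDX39B had 2632, 3813 and 3785 counts, SRXN1 had 3401, 2920 and 3488, and NFAT5 had 5136, 1141 and 1515. Each of the 3 annotations overlaps its gene on the same strand, so a different assignment of reads cannot be excluded for any of them. DESeq2 called 14 genes, 8 higher and 6 lower, with 514 at an unadjusted p under 0.05, and edgeR without a filter on low counts called 70, 40 higher and 30 lower. The 14 included all 3 above, as well as GDF15, NFAT5, SLC6A6, COL4A1, LAMA4, LGSN, ZNF84, 3 further readthrough genes and KCTD20, the last of which had 576, 2609 and 3496 counts and was named after its values were seen.

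By size alone, 649 genes were at least 2-fold higher and 290 at least 2-fold lower in both knockdown libraries than in the control. Independent lists of the same lengths would share 121.1 and 86 genes. Simulations without an effect, in which both libraries share the lone control and all libraries vary alike, gave 564 higher genes on average. They gave 598 higher genes at most, and 349 lower genes on average. The simulations drew only genes that had passed the filter in the real counts. A gene low in the control could pass it through a knockdown library alone, so the filter itself may add to the 649. With knockdown library 2 set alone against the others, 1343 genes differed 2-fold from both, and with knockdown library 1 alone 701, against 939 for the control. Scales that shrink low counts gave fewer genes: 286 higher and 178 lower with a prior count of 10, where the simulations gave 288 and 188 on average, and 61 higher and 70 lower on the log2(CPM + 5) scale, against 86.2 and 54.8. With no filter on low counts 1071 were higher and 673 lower. Among the 11236 genes with a mean of at least 100 counts, 153 were higher and 115 lower in both, 268 together, fewer than the 339 ± 20 (SD over 20 simulations) of the simulations. With knockdown library 1 as the lone library 249 of these genes differed 2-fold from both, and with library 2 557.

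The largest higher values by the naming rule included 2 basement membrane genes, COL4A1 and LAMA4. COL4A1, a chain of type IV collagen, had 32, 243 and 257 counts and log2 changes of 2.76 and 2.71. LAMA4, a laminin chain of basement membranes, had 167, 1205 and 921 counts (2.75 and 2.23). The zinc finger gene ZNF84 had 90, 681 and 684 counts (2.80 and 2.68), and LGSN, which encodes the lens protein lengsin, had 57, 364 and 446 (2.55 and 2.70). ZNF227, CGA and EME2 were also among the 10 highest, with less even values: ZNF227 was at 3.50 and 1.76, EME2 at 3.03 and 2.15, and CGA, the shared alpha subunit of glycoprotein hormones, at 1.15 and 4.07. COL4A1 overlaps COL4A2 at its end on the other strand, ZNF227 overlaps ZNF235, and EME2 overlaps SPSB3, so their reads cannot be separated with certainty. The 10 highest also held the readthrough genes PTGES3L-AARSD1 (3, 145 and 279 counts) and ATP5J2-PTCD1 (30, 508 and 323 counts). None of the 10 passed the edgeR threshold over all genes.

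The lowest values included a stress cytokine, an osmotic stress regulator and a taurine transporter. GDF15, a cytokine of the TGF-beta superfamily that is released under cell stress, had 3163, 742 and 487 counts (log2 changes -2.18 and -2.92). NFAT5, the transcription factor of the response to osmotic stress, was at -2.26 and -1.98. SLC6A6, which encodes the taurine transporter, had 2867, 496 and 760 counts (-2.62 and -2.14). The secreted protein gene SCUBE3 was at -1.79 and -2.96, FAM101B at -1.75 and -2.79, CCDC117 at -2.67 and -1.65, BAHCC1 at -1.47 and -2.65, and PARVB, a focal adhesion protein whose gene overlaps SAMM50, at -1.63 and -2.25. Adjusted p-values over all genes (edgeR) were 0.178 for GDF15 and SLC6A6, 0.187 for NFAT5 and ZNF84, 0.449 for COL4A1 and 0.353 for LAMA4. GDF15 passed when adjusted over the list alone, in the list of p53 targets and in that of ATF4 targets (adjusted p = 0.00267 in each).

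**Figure D1:**
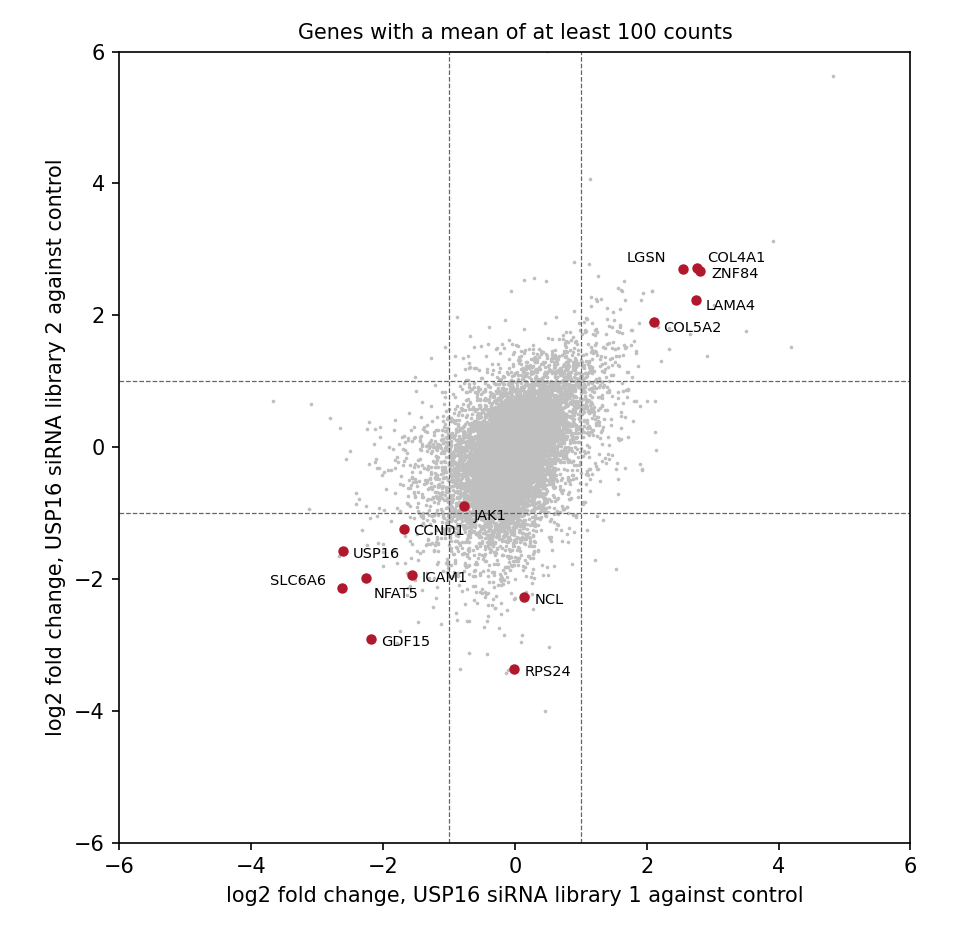
Log2 fold change of each gene against the control library in USP16 siRNA library 1 (horizontal axis) and library 2 (vertical axis), 1 grey point per gene with a mean of at least 100 counts, red points for the labelled genes, and dashed lines at 2-fold. COL4A1, ZNF84 and LGSN lie near 2.7 on both axes, SLC6A6 and NFAT5 near -2 or below, and RPS24 is low in library 2 alone. The plot shows 11232 genes, and 4 genes lie outside the axes.

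Targets of STAT3 and STAT5, the transcription factors activated by cytokine receptors through JAK kinases, were lower as a group. Of the 26 members measured, 17 were lower and 4 higher in both knockdown libraries, with list medians of -0.39 and -0.49 (camera, adjusted p = 0.00464). With an estimated correlation the call was lost (adjusted p = 0.805), as it was with fry (adjusted p = 0.555). At 1 residual degree of freedom both had too little power to speak for or against the call. ICAM1, an adhesion molecule, had 3621, 1301 and 1100 counts (-1.57 and -1.94), and CCND1, which encodes cyclin D1, had 22204, 7325 and 10971 counts (-1.69 and -1.24). These 2 genes fell when adjusted over the list alone (edgeR, adjusted p = 0.0176 for each), and no member passed over all genes. The feedback inhibitor SOCS2 was at -2.41 and -0.87, the protease inhibitor TIMP1 at -1.08 and -1.07, and the survival factor MCL1 at -0.89 and -0.85, the last 2 named after their values were seen. BCL2L1, a survival factor as well, was at 1.07 and 0.93, and MYC, with 40, 50 and 201 counts, at 0.22 and 2.05. The list median lay at percentile 0.02 of expression-matched random lists. With knockdown library 1 set alone against the control and knockdown library 2, the list was called too, lower in library 1 (camera, adjusted p = 0.00959), and with knockdown library 2 alone it was not (adjusted p = 0.920).

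The 28 JAK-STAT components themselves did not pass (camera, adjusted p = 0.116), with medians of -0.20 in both libraries and 15 members lower and 6 higher in both. JAK1 had 5350, 3322 and 3349 counts (-0.78 and -0.90, edgeR adjusted p = 0.999 over all genes and 0.245 adjusted over the list alone). The interferon receptor chains IFNAR1 and IFNAR2 were at -1.51 and -0.75, and at -0.97 and -1.21. STAT3 was at -0.21 and 0.72. On the opposite strand, JAK1 overlaps RAVER2 and CCND1 overlaps ORAOV1. NF-kB targets had medians of -0.86 and -0.09 (camera, adjusted p = 0.0719), with 9 of 21 lower in both and 0 higher in both, and they passed with no filter on low counts (adjusted p = 0.00645) but not with an estimated correlation (adjusted p = 0.805). They include ICAM1, which fell when adjusted over the list alone (adjusted p = 0.0165), and the chemokine CCL2, at -1.19 and -2.12. Interferon-stimulated genes were at -0.46 and -0.05 (39 genes, adjusted p = 0.290), and feedback and immediate-early genes of the MAPK pathway at -0.39 and -0.21 (31 genes, adjusted p = 0.241). CCND1 passed when adjusted over the list alone there too (adjusted p = 0.0419), whereas the receptor EPHA2, with a mean log2 change of -1.22 ± 0.04 (SD, n = 2), did not (adjusted p = 0.105).

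Replication-dependent histone genes were higher as a group. Of 15 measured, 11 were higher and 0 lower in both libraries, with medians of 0.84 and 0.72 (camera, adjusted p = 0.00907). The median of the mean change was 0.70, and 0.50 with no filter on low counts. Members such as HIST1H3B, with 2, 10 and 8 counts, may have passed the filter only through their higher side. With an estimated correlation the call was lost (adjusted p = 0.805), and likewise with fry (adjusted p = 0.390) and with a minimum mean of 100 counts (adjusted p = 0.0744). The first 2 had little power at 1 residual degree of freedom, and the estimated correlation itself, -0.0286, lay below the preset value. Most mRNAs of this class lack a poly(A) tail, and the levels were low: all 15 together had 722 counts in the control and 1366 and 1400 in the knockdown libraries, or 54.2, 96.4 and 90.0 CPM. HIST1H2BD had 23, 74 and 90 counts (1.52 and 1.67), HIST1H2BE had 8, 18 and 25 (0.93 and 1.24), and HIST2H2BE had 85, 120 and 267 (0.40 and 1.41). No histone gene passed when adjusted over the list alone. These genes have near-identical copies, so single members are uncertain.

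Chromatin groups tied to H2A ubiquitination did not pass as lists. The 14 H2A deubiquitinases had medians of -0.10 and -0.19 (camera, adjusted p = 0.367), and the 31 Polycomb subunits of -0.02 and -0.12 (adjusted p = 0.498). PHC1, a subunit of the complex that places the H2A mark, was at -0.91 and -1.76, and JARID2, a cofactor of the complex that methylates histone H3, at 0.77 and 0.80. The 34 HOX genes, classic Polycomb targets, had medians of -0.25 and -0.19 (adjusted p = 0.459), with 13 lower and 9 higher in both. HOXB9 was at 0.85 and 2.80, and HOXC13 at -0.69 and -1.53.

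No cell cycle list passed. G1/S genes had medians of -0.07 and -0.20 (54 genes, camera adjusted p = 0.161) and G2/M genes of -0.01 and -0.21 (63 genes, adjusted p = 0.498). In G2/M, the centromere chaperone HJURP was at -2.09 and -1.05 and the mitotic kinase AURKA at -0.77 and -1.04, while the mitotic kinesins CENPE (1.37 and 1.37) and KIF20B (1.16 and 1.21) were higher. PLK1 was at -0.17 and -0.92. The p53 targets were at -0.16 and -0.08 (37 genes, adjusted p = 0.161) and CDK inhibitors at -0.11 and -0.05 (11 genes, adjusted p = 0.427). CDKN1A, the gene of the p21 inhibitor, had 2935, 790 and 1773 counts (-1.98 and -0.95, adjusted p = 0.196 over the p53 list alone). Apoptosis regulators were near 0 (-0.01 and -0.02, 32 genes, adjusted p = 0.503), and within them BMF, a proapoptotic member of the BCL2 family, fell when adjusted over the list alone (-1.67 and -1.76, edgeR adjusted p = 0.0425) but not over all genes. DNA repair genes were at 0.09 and 0.17 (32 genes, adjusted p = 0.498).

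Among stress and protein quality lists, heat shock genes, ATF4 targets and proteasome subunits had positive medians in both libraries, and no list passed camera. Heat shock genes had medians of 0.27 and 0.27 (18 genes, camera adjusted p = 0.241), with HSP90AA1 at 0.90 and 1.10 and HSPD1 at 0.96 and 0.91. ATF4 targets of the integrated stress response were at 0.23 and 0.12 (37 genes, adjusted p = 0.427), and in this list DDIT3, a transcription factor of the same response, was at 0.93 and 1.60, opposite in sign to GDF15. Chaperones of the unfolded protein response were at 0.18 and -0.07 (23 genes, adjusted p = 0.849), and proteasome subunits at 0.06 and 0.23 (31 genes, adjusted p = 0.487). NRF2 targets were at -0.15 and -0.37 (28 genes, adjusted p = 0.441). The aldo-keto reductase AKR1C2 (1.67 and 2.23), which has near-identical copies, stood against HMOX1, the heme-degrading enzyme, at -0.73 and -2.64. The list of siRNA machinery genes was at -0.31 and -0.05 (13 genes, adjusted p = 0.498).

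Ribosomal protein genes had unlike medians in the knockdown libraries, 0.04 in library 1 and -0.28 in library 2 (79 genes, camera adjusted p = 0.0719, and between 0.0238 with no filter on low counts and 0.805 with an estimated correlation). Of the 79, 28 were lower in both libraries, 11 higher in both and 40 opposite in sign. RPS24 had 16897, 17886 and 1912 counts, RPS12 had 5785, 7075 and 1408, and RPS15 had 5259, 4075 and 1331, while RPS3, with 9272, 5595 and 5166, was at -0.82 and -1.07. The nucleolar protein gene NCL had 20622, 24209 and 4975 counts, and the ribosome assembly factor RRS1 had 1213, 1286 and 289. Ribosome biogenesis genes as a list were at 0.15 and 0.04 (49 genes, adjusted p = 0.487), with NOLC1, a nucleolar chaperone, at 1.52 and 1.29, and MYC targets were at 0.14 and 0.06 (31 genes, adjusted p = 0.568). Ribosomal protein genes have many processed pseudogenes, so single members are uncertain, and a difference between the knockdown libraries in a given gene was not tested, since each is a single library.

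Transcripts encoded by the mitochondrial genome were lower in both libraries for 12 of 13 genes, with medians of -0.40 and -0.38 (camera, adjusted p = 0.116). They passed without a filter on low counts (adjusted p = 0.0139) and with the DESeq2 statistic (adjusted p = 0.0438), and other alternatives gave up to 0.805, the value with an estimated correlation. MT-ND4 was at -0.45 and -0.59. Nuclear subunits of oxidative phosphorylation were at 0.04 and -0.05 (44 genes, adjusted p = 0.840). Glycolysis genes were at -0.26 and -0.28 (20 genes, adjusted p = 0.161), with the lactate exporter SLC16A3 at -1.49 and -1.33 and the pyruvate kinase gene PKM at -1.15 and -0.78. Hypoxia genes were at -0.25 and -0.02 (28 genes, adjusted p = 0.498). Lipid lists had unlike medians in the libraries: cholesterol synthesis was at -0.28 and 0.57 (24 genes, adjusted p = 0.498), with 17 of 24 members opposite in sign, and fatty acid synthesis at -0.54 and 0.06 (16 genes, adjusted p = 0.498). The malic enzyme gene ME1 was at 1.54 and 1.76, and SCD, the stearoyl desaturase, at -1.70 and -0.28.

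In the mesenchymal list, 2 genes passed when adjusted over the list alone, and none over all genes. COL5A2, a chain of fibrillar collagen, had 242, 1114 and 1055 counts (2.10 and 1.89), and POSTN, which encodes the matrix protein periostin, had 0, 22 and 30 counts and was at least 6.89-fold and 8.56-fold higher. Both rose when adjusted over this list of 33 genes alone (edgeR, adjusted p = 0.0236 for each). The list as a whole did not pass (camera, adjusted p = 0.568). Its medians were -0.11 and -0.09, and that of the mean change, -0.08, was the same with the genes at 0 counts set at their bounds, while its mean, 0.16, and the test pointed up, and TWIST2, a transcription factor of the same list, was at -1.02 and -1.84. COL4A1 rose when adjusted over the list of TGF-beta targets alone (adjusted p = 0.0118). In that list, too, the median of -0.05 and the mean of 0.09 differed in sign (22 genes, camera adjusted p = 0.683). The epithelial list had a median of 0.07 and a mean of -0.02 (26 genes, camera adjusted p = 0.767), with the adhesion molecule EPCAM at 1.94 and 2.33 and the transcription factor ELF3 at -1.97 and -1.57.

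Growth factor and marker lists did not pass. The EGFR family and its ligands were at 0.05 and -0.47 (13 genes, camera adjusted p = 0.459), and the ligand EREG (1.62 and 2.37) stood against the receptor EGFR (-0.35 and -1.89). YAP and TEAD targets were at -0.19 and -0.32 (22 genes, adjusted p = 0.427). Among lung epithelial markers (8 genes, adjusted p = 0.816), with a median of -0.13 and a mean of 0.11, TP63, the basal cell transcription factor, had 11, 62 and 82 counts and rose when adjusted over the list alone (edgeR, adjusted p = 0.0466). It did not pass over all genes. Neuroendocrine markers were at 0.01 and 0.08 (7 genes, adjusted p = 0.498), immune cell markers at 0.23 and 0.50 (7 genes, adjusted p = 0.370), and fibroblast and endothelial markers at -0.01 and 0.28 (8 genes, adjusted p = 0.291). In the last list, COL3A1 had 19, 67 and 94 counts and ACTA2, the smooth muscle actin gene, had 47, 114 and 249.

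**Figure D2:**
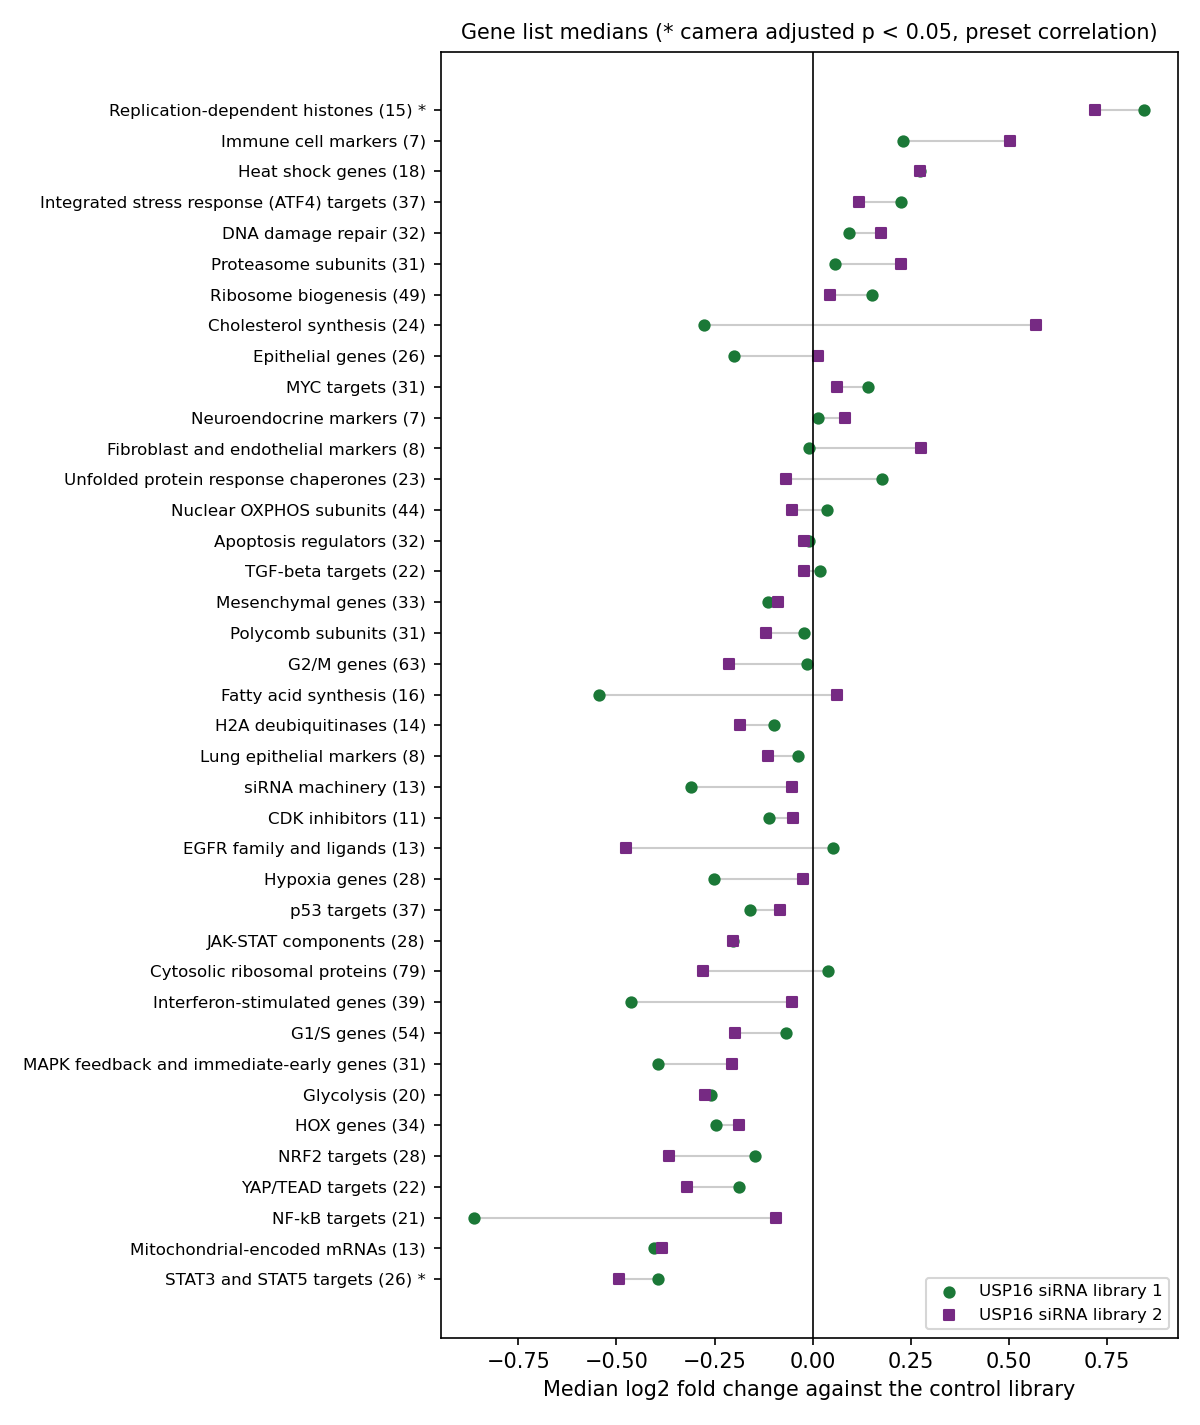
Median log2 fold change against the control library of each of the 39 gene lists, in USP16 siRNA library 1 (green circles) and library 2 (purple squares), with the number of measured genes in brackets and an asterisk at the lists past the camera threshold. The 2 lists with an asterisk are the histone genes (0.84 and 0.72) and the STAT3 and STAT5 targets (-0.39 and -0.49), and cholesterol synthesis spans -0.28 to 0.57.

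Over all lists, 2 of 39 passed camera at its preset correlation, 0 with an estimated correlation and 0 with fry, whose lowest adjusted p was 0.328. With 1 residual degree of freedom, the outcome of the last 2 tests was nearly fixed by the design. Each knockdown library set alone against the others also gave called lists at the preset correlation, at least as many as the real split. The medians of 13 lists lay outside the central 95% of expression-matched random lists, with heat shock genes at percentile 99.97 and ATF4 targets at 99.91. Adjusted over the list alone, 12 members of 10 lists passed, counting a gene in each list that holds it. USP16 itself is among them, none passed over all genes, and these values were not adjusted across the 39 lists. Across genes, which are not independent replicates, the log2 changes of the 2 knockdown libraries correlated at r = 0.512. Simulations without an effect, with all libraries varying alike, gave 0.508 ± 0.0049 (SD over 20 simulations) because both changes share the control. The covariance was 0.305 against a simulated 0.274, and among genes with a mean of at least 100 counts it was 0.173 against 0.201, with r = 0.461 against a simulated 0.505 ± 0.0051. At a mean of at least 100 counts, the variance from the control was 0.304 for knockdown library 1 and 0.461 for knockdown library 2. The libraries thus did not vary alike, and the simulated values cannot say how much agreement sharing gives here. With 1 control library the controls could not be split, so part or all of the agreement may come from the shared control.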

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

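The removal of readthrough genes and the settings with a knockdown library as the lone one were chosen after seeing the data. No result changed sign while past its threshold under any alternative. Median-ratio size factors and the removal of readthrough genes left the counts of genes and lists within 1.5 times, USP16 on the same side of the threshold and the agreement within its simulated SD. With no filter on low counts 70 genes were called (40 higher, 30 lower), USP16 passed at -2.10, 5 lists passed, and 1071 genes were 2-fold higher and 673 lower in both libraries. With a minimum mean of 100 counts 1 gene was called, a lower one, 1 list passed, 170 and 91 genes were 2-fold, since the TMM factors were computed anew from these genes (153 and 115 with the factors from all genes tested), and the agreement was r = 0.461, below the 0.505 of simulations without an effect for genes at these counts. DESeq2 called 14 genes (8 higher, 6 lower) and its statistic gave 4 lists, while camera with an estimated correlation and fry gave 0 lists each. The outcome of these last 2 was nearly fixed by the 1 residual degree of freedom, and the cause of the other differences was not tested. The 2-fold counts were 61 higher and 70 lower on the log2(CPM + 5) scale (r = 0.468, simulated 0.504) and 286 and 178 with a prior count of 10 (r = 0.492, simulated 0.506), since both shrink low counts. With 1 knockdown library left out, which leaves values with no test, 1219 to 1718 genes were 2-fold higher and 959 to 1551 lower, since the rule then asks for 1 library, and USP16 stood at -2.60 to -1.58. With knockdown library 1 as the lone library 429 genes were higher in the others, and with library 2 572 were lower.

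No paired analysis was possible because the control group has 1 library. Pseudocounts do not enter the count tests and were run only for fold changes per library. Of the 167 genes besides USP16 that the naming rule gave, 20 passed without the filter and 9 with DESeq2 that did not in the edgeR test, and 0 lost their call where they were tested, 2 of the 3 called genes being under the minimum mean of 100 counts. Over 17287 genes, 6% of simulated 2-fold changes were recovered.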

Other observations

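The changes of genes spanned by readthrough genes, the comparison of knockdown libraries at high counts and the count of genes called in other splits were tests chosen only after the results were seen.

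Readthrough genes held many of the most extreme values: 17.3% of the 75 tested, against 5.38% of other genes, were 2-fold in both knockdown libraries. They had an SD of 1.85 in mean log2 change, against 0.746 on average in 1000 sets of other genes matched on mean count, a ratio of 2.48, which argues against few reads as the reason. At the 17 whose change in CPM was at least 10% of the mean level of the locus, the genes they span changed the other way in 11 (64.7%, exact binomial 95% interval 38.3 to 85.8), and the median ratio of the 2 changes was -0.606, where reads that only moved between annotations would give -1. ATP6V1G2-DDX39B with its parts had 3292, 3826 and 3810 counts, and BLOC1S5-TXNDC5, alone at 0, 0 and 2627, had 4203, 4038 and 3332 with its parts. Since the interval holds 50%, reads moved between annotations stay open for the loci as a set, and no biological explanation, such as altered readthrough, was tested.

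For the STAT3 and STAT5 targets, the list median stayed at percentile 0.1 of random lists matched on expression, GC content and transcript length, which argues against GC content, transcript length or expression level of the list members as the cause. Setting knockdown library 1 alone against the others gave 7 lists past the threshold, the STAT targets among them, and library 2 alone gave 2, as many as the control, which were ribosomal proteins and cholesterol synthesis and not the STAT targets (adjusted p = 0.920). That any library set alone against the other 2 gives some called list may therefore hold at the preset correlation, while this list was not called with every library. An effect of USP16 knockdown on these genes stays open, as the control is a single library.

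The knockdown libraries differed from each other as much as from the control: at a mean of at least 100 counts, the variance between them was 109.8% of their mean variance against the control. Counting error alone would also make the pairs alike, so this ratio cannot tell whether few reads per gene are the reason. The chi-square of 62.5 per degree of freedom between them is far above what counting error gives, which argues against few reads. A smooth GC trend removed 2.85% of the variance between the knockdown libraries, which argues against GC content. Different siRNAs with different off-target effects or a difference in the degree of knockdown (83.8% and 66.8%) may contribute and remain untested. The library with the weaker knockdown was the further from the control (variance 0.461, against 0.304 for the other). It also stood at a variance of 0.42 from the other knockdown library, so its own spread may make up part of that distance. The order therefore cannot speak for or against a graded effect. For the genes called, 3 splits of the libraries are too few for a share under 0.05. No other split called as many genes past the threshold as the real one, but the margin was too small to set the real split apart. At an unadjusted p under 0.05 (edgeR), though, the split with knockdown library 2 alone held more genes than the real one.

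A hypothesis drawn from the lower NFAT5 and SLC6A6 was that other osmotic stress targets of NFAT5 would be lower as well. Of 10 such genes listed before their values were looked at, some of them members of lists in the report, 8 were measured, and their median was -0.34, at percentile 3.27 of matched random lists, which lies between the bounds set in advance and leaves the hypothesis open. SLC5A3, the myo-inositol transporter, was at -0.83 and -0.27, AKR1B1, aldose reductase, at -0.41 and -0.22, and S100A4 at -1.05 and -1.16. The heat shock genes HSPA4L (0.64 and 0.21) and HSPA1B (0.62 and 0.20) were higher in both, and the amino acid transporter SLC38A2 was at -0.18 and 0.51, so that 5 of the 8 were lower in both and 2 higher in both.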
